A study of Mus musculus with 30 samples.

How the data were processed

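RNA was measured in 30 libraries of primary dorsal root ganglion (DRG) cultures from C57/Bl6 wild-type mice. Neurons had been enriched, and a PHP.S adeno-associated virus, which targets sensory neurons, had carried either A-Fos or GFP into them. A-Fos is a dominant negative form of Fos that binds Jun proteins and keeps them off DNA, and its libraries are called DN here. GFP libraries were the control for the vector, and untransduced libraries had received no virus. Each condition had 10 replicates. The sample titles separated 3 culture sets, called plain (replicates 1 to 3), 7DIV (replicates 4 to 6, with 7 days in vitro in the title) and dated (replicates 7 to 10). The series design states that the culture of each mouse was divided between the 3 conditions, so libraries with the same replicate number were treated as parts of 1 culture. Because the labels do not name the mouse of each library, this was checked in the counts: after the effects of condition and culture set were taken off, same-number pairs correlated above 0.1 across genes in 8 of 30 cases, with a median r of 0.063 against -0.02 for the means of differently numbered pairs of the same set. Genes are not independent replicates in that correlation. Deviations from the mean of a condition and set cancel out. This ties the value for differently numbered pairs to that of same-number pairs with opposite sign, so it is no independent reference. The labels gave extraction with the RNeasy Micro kit and library construction with a TruSeq kit.

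The deposited gene table held raw read counts per Ensembl gene, and the deposited repeat table held raw read counts per short genomic interval. The submitters' processing notes name bcl2fastq 2.17, STAR and HTSeq with the GRCm38/mm10 build. The settings, the strandedness and the annotation release are not given in the sources used here, nor is the way the intervals were chosen. No normalization by the authors was found in either table: all values were whole numbers and library totals differed. Gene symbols and positions came from the GENCODE M21 annotation, which gave a symbol for 48349 of 48795 gene identifiers. Expression of the A-Fos and GFP transgenes was not analysed here.

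Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by the filterByExpr function by condition with its default settings (18063 of 33717 genes with any count), scaled with TMM factors and fitted with robust quasi-likelihood models. A single model held all 30 libraries, with condition and with replicate number as a block that also takes up culture set. Contrasts were tested two-sided with the quasi-likelihood F test, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Whether the DN effect differed between culture sets was tested with the interaction coefficients of set and condition. The standard error (SE) of a log2 fold change was the fold change divided by the square root of its F statistic. Levels are CPM, counts scaled to 1e+06 by the TMM-scaled totals, given as mean ± SD over 10 libraries. The log2 CPM used for averages carried a prior count of 2. Expression of a gene with no count in a library is limited to 3 counts of that library's total, and this limit covers counting error only.

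Of 30 gene lists that had been fixed, 29 were tested, since a list needed at least 3 members past the filter, and 1 list, of T cell, B cell and neutrophil markers, had 1 of 17. Lists were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation, with fry, and by an exact sign-flip test (two-sided, smallest possible p 0.00195) on the 10 within-replicate differences of the list's mean log2 CPM relative to all tested genes. The last of these was added after the data were seen. Members past the threshold were counted over all genes tested and adjusted over the list alone. Named genes followed a rule: the 12 largest rises and 12 largest falls of DN against GFP, and 6 and 6 for the other contrasts, among genes past the threshold with a mean of at least 2 log2 CPM and 1 direction in all 3 sets, every member of the AP-1 family list, up to 4 members per list with the smallest p, 6 genes for the difference between sets and 6 LINE subfamilies per contrast. Other members named beside a list were chosen after their values were seen. The values of some genes that the rule names, or that passed in a list, are not reported here, whatever they were under the alternatives, and are left out of the tallies of alternatives. The lists and the rule were chosen before the data were examined. So were the tests and alternatives that are not described as added or unplanned.

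Repeat intervals were assigned to classes by the annotation in the table. LINE counts were summed per subfamily and tested with edgeR on the library sizes and factors of the gene table. LINE, SINE, LTR and rRNA reads per gene read were compared by exact two-sided sign-flip tests of the 10 within-replicate log2 differences. The SINE, LTR and rRNA comparisons were added after the data were seen. The mitochondrial share of counts was compared between conditions by the same test, which had not been planned in advance. Intervals were placed in exons, in genes outside exons or outside genes with GenomicRanges 1.54.1.

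The alternatives were DESeq2 1.42.0, limma 3.58.1 with voom, median-ratio and upper-quartile factors, no filter and a filter of 1 CPM in 10 libraries, no block, no block and no set term, a fit of the compared groups alone, a test against a fold of 1.2, no robust estimation, each culture set alone or left out, and each replicate number left out. Fits without untransduced replicate 4, which stood apart, and LINE intervals outside genes were added after the data were seen. Labels were also swapped within replicates and the data refitted, in 50 arrangements per comparison with the real one included, and for the difference between sets the replicates were moved between sets. The procedure was tested on simulated data drawn at the depth and spread of the libraries. Among 17835 genes of which 200 had been changed, DN against GFP recovered 86% of 1.5-fold, 94% of 2-fold and 100% of 3-fold changes, and 10 of 200 calls were of unchanged genes. With no change put in, GFP against untransduced gave 0 calls. The changed genes were drawn from those with an average above 0 log2 CPM, and no simulated library was made to stand apart. A 4-fold difference between culture sets was recovered for 87% of genes, and 7 of 10 LINE subfamilies changed 2-fold were recovered. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.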

Results

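Gene expression was measured by RNA sequencing in 30 libraries of DRG neuron cultures: 10 with the AP-1 inhibitor A-Fos (DN), 10 with GFP and 10 untransduced. Each condition had 3 libraries in the plain set, 3 in the 7DIV set and 4 in the dated set. The gene counts of a library summed to between 10.7 and 39.1 M (M, 1e+06 counts). The lowest total belonged to untransduced replicate 4, and the next lowest was 24.1 M. Group means were 27.4 M ± 7.54 (SD, n = 10) for untransduced, 31.6 M ± 3.47 for GFP and 30.7 M ± 4.45 for DN. Of 48795 genes in the table, 33717 had a count in any library and 18063 passed the filter. The first principal component held 34.22% of the variance and the second 10.96%, and the common biological coefficient of variation was 0.18. Untransduced replicate 4 also stood apart in the nuclear RNA Malat1, at 42200 CPM against 1900 to 8250 in the other 29 libraries, so counts are also given without it where they move by over 1.5 times.

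The comparison of DN with GFP asked what inhibiting AP-1 changes in DRG neurons beyond transduction itself. The largest rise was in Mrgprd, the receptor that marks nonpeptidergic nociceptors, at 45.5 CPM ± 15.0 (SD, n = 10) in DN against 3.59 ± 2.40 in GFP and 3.95 ± 2.42 in untransduced cultures, a 14.0-fold difference (log2 fold change 3.81, SE 0.32, adjusted p = 3.51e-08). Tac1, which encodes the neuropeptide substance P, rose 4.89-fold from 19.4 ± 9.30 to 85.9 ± 20.9 CPM, and Ptgir, the prostacyclin receptor, rose 4.14-fold from 22 ± 3.04 to 91.1 ± 13.0 CPM with the smallest adjusted p of the comparison (2.17e-14). Among the falls, Cckbr, a cholecystokinin receptor, went from 12.2 ± 3.89 to 1.89 ± 1.56 CPM (6.98-fold), Serpinb1a from 186 ± 41.3 to 31.1 ± 16.1 CPM (6.47-fold) and Nts, the neurotensin precursor gene, from 27.4 ± 7.46 to 5.32 ± 4.13 CPM (5.78-fold). Each of these 6 genes moved in its direction in 10 of 10 replicates.

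On GRCm38, Mrgprd (ENSMUSG00000051207) lies on chromosome 7 from 145314835 to 145324086, Ptgir (ENSMUSG00000043017) on chromosome 7 from 16906490 to 16910905, Cckbr (ENSMUSG00000030898) on chromosome 7 from 105425731 to 105470898 and Serpinb1a (ENSMUSG00000044734) on chromosome 13 from 32842092 to 32851185. The other large rises were Alkal2 (6.82-fold), Ctxn3 (5.08-fold), Chp2 (4.59-fold), Hoxd1 (4.56-fold), Ldb2 (3.93-fold), Rasgrp1 (3.22-fold), Dgkg (3.17-fold), Paqr5 (3.10-fold) and Pde11a (3.01-fold). The other large falls were Trappc3l (4.86-fold), Sez6l (4.73-fold), Draxin (3.94-fold), Ecel1 (3.74-fold), Tgfbi (3.57-fold), Fam19a4 (3.48-fold), Gm16334 (3.43-fold), Rasd2 (3.28-fold) and Tecta (3.08-fold). All 18 were past the threshold and moved in their direction in 10 of 10 replicates. Within the plain, 7DIV and dated sets the log2 fold change of Mrgprd was 4.95, 2.91 and 3.67 and that of Ptgir 2.28, 1.80 and 2.05. In the 7DIV set alone, with 3 replicates, the adjusted edgeR p of Mrgprd (ENSMUSG00000051207), DN vs GFP, was 0.134 and that of Cckbr (ENSMUSG00000030898), DN vs GFP, was 0.127, so neither passed there, with folds in the same direction as over all sets. That fit also held untransduced replicate 4, which stood apart.

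**Figure D1:**
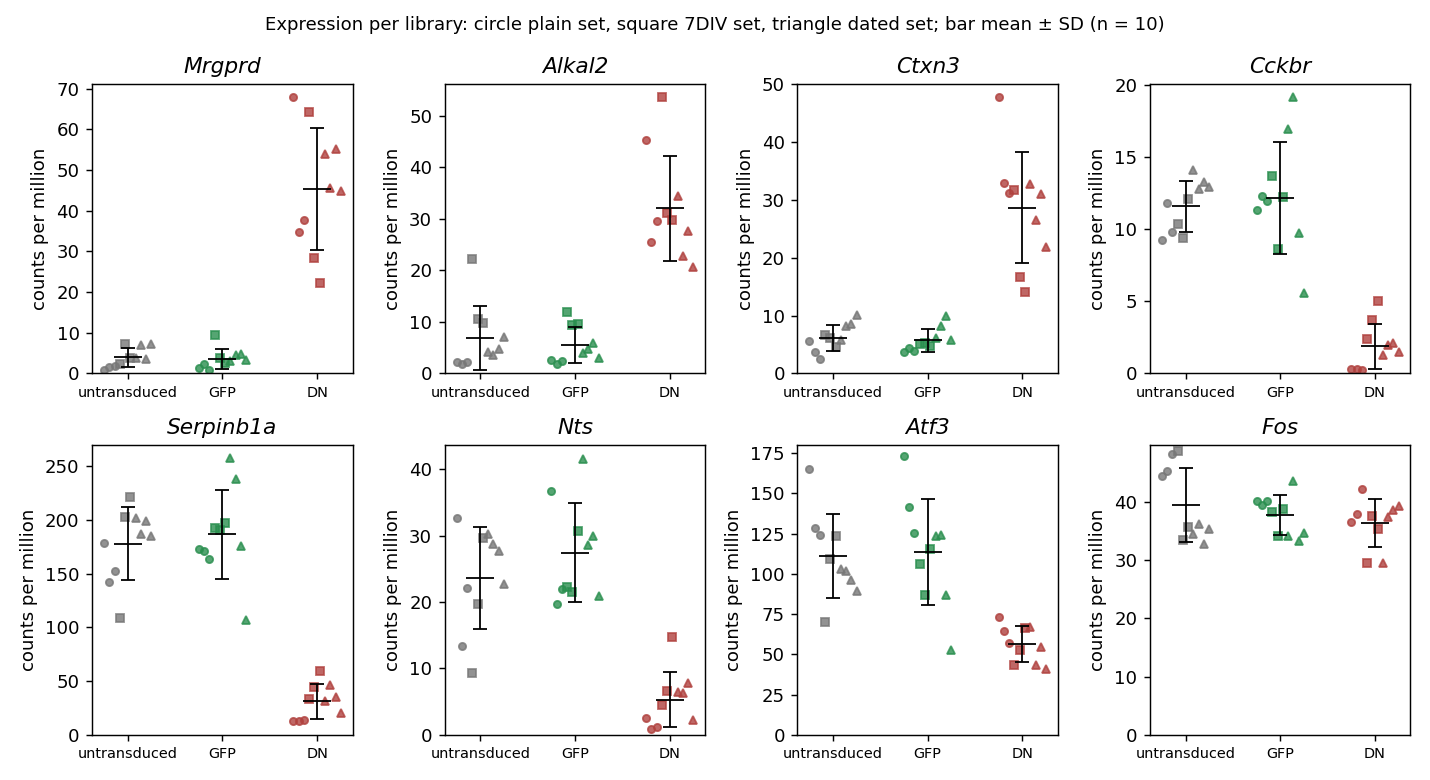
Each point is 1 library, with TMM-scaled CPM on the vertical axis and condition on the horizontal axis, and bars give the mean and SD of 10 libraries per condition. The DN libraries of Mrgprd lie above those of both controls (45.5 ± 15.0 against 3.59 ± 2.40 CPM in GFP), those of Serpinb1a lie below them, and the mean of Fos differs little between conditions.

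Across all genes, 2054 of 18063 were past the threshold in DN against GFP by edgeR, 1442 higher and 612 lower, of which 178 rose and 123 fell by at least 2-fold. Of the 2054 genes, 2025 had the same direction in all 3 culture sets. They had been called from these sets together, so this agreement is no independent check. The share that was higher depended on scaling: it was 70.2% with TMM factors, 63.13% with median-ratio factors and 57.11% with upper-quartile factors. Without the replicate block, 2010 genes passed with culture set as a covariate and 973 with no set term. The plain set alone gave 4004 genes, the dated set alone 751 and the 7DIV set alone 10. The 7DIV fit included untransduced replicate 4, so its low count does not show that the effect was absent there. In that fit 2027 of the 2054 genes kept their direction, although they had been called with these libraries included. Over all sets, 3239 genes passed without untransduced replicate 4. That library contributes to the spread and the block of the main fit although it is in neither group.

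**Figure D2:**
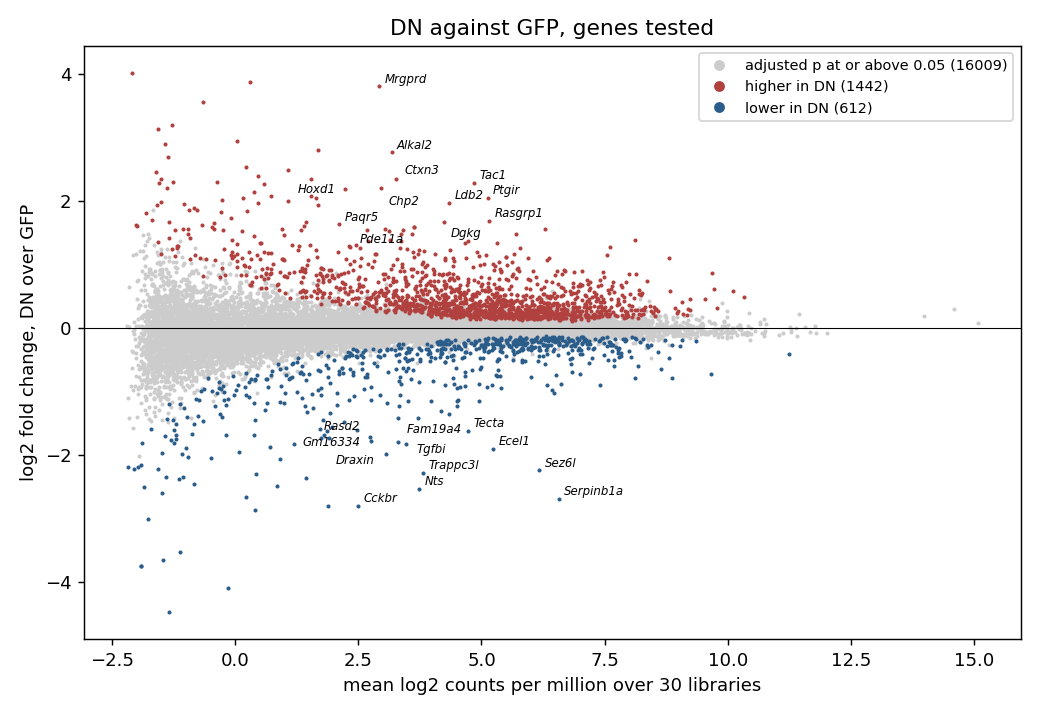
Each point is 1 of 18063 genes, with mean log2 CPM over 30 libraries on the horizontal axis and the log2 fold change of DN over GFP on the vertical axis. The 1442 genes past the threshold above 0 and the 612 below it are coloured, and the 24 genes with the largest changes under the naming rule are labelled.

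Of 18 AP-1 family genes tested, 3 fell in DN and 15 did not pass. Atf3, a stress-induced AP-1 partner gene on chromosome 1 (191170296 to 191218039, ENSMUSG00000026628), fell 1.98-fold from 113.5 ± 33.1 to 56.4 ± 11.3 CPM (log2 fold change -0.98, SE 0.09, adjusted p = 4.60e-08, lower in 10 of 10 replicates). Fosl1 fell 1.25-fold (adjusted p = 0.0205, 9 of 10 replicates). Fos was at 36.3 ± 4.04 CPM in DN and 37.6 ± 3.43 in GFP, a log2 difference of -0.05 (SE 0.07, adjusted p = 0.760), and how reads of the A-Fos transgene were counted was not analysed here. Of the members that did not pass, Fosb, Fosl2, Jun, Junb, Jund, Batf3, Jdp2, Maf, Maff, Mafg, Mafk, Mafa, Atf2 and Atf7, had log2 differences between -0.22 for Fosb and 0.11 for Jun. The count adjusted over the list alone was also 3, and camera gave an adjusted p of 0.0127 at the preset correlation, which was 0.195 with an estimated correlation and 0.00187 by fry. The list's mean was lower in 10 of 10 replicates (mean log2 difference -0.14, exact sign-flip test, adjusted p = 0.00944). The adjusted p of Fosl1 (ENSMUSG00000024912), DN vs GFP, was 0.0613, 0.0506 and 0.0570 without replicate 3, 8 or 10, in a range of 9.09e-05 to 1.00 over all its alternatives.

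Of 26 textbook AP-1 target genes, 3 fell and none rose: Plaur, the urokinase receptor (1.69-fold, adjusted p = 7.72e-07), Sprr1a (4.12-fold, adjusted p = 0.00265, from 1.36 ± 0.99 to 0.35 ± 0.42 CPM) and Bcl2l11 (1.24-fold, adjusted p = 0.00649). Plau was 1.14-fold lower with an adjusted p of 0.222. Of 24 immediate early genes, 5 fell and none rose, with Dusp1, a MAP kinase phosphatase, at 65.0 ± 8.77 CPM against 109 ± 20.6 in GFP (1.67-fold lower, 10 of 10 replicates), Csrnp1 and Btg2 at 1.25-fold and 1.21-fold lower, Sik1 at 1.15-fold lower, and Egr2, chosen after its value was seen, at 1.15-fold lower. Counts adjusted over the list alone were 3 and 6. With an estimated correlation the adjusted p of the target list was 0.534 and that of the immediate early list 0.195, against 0.00101 and 0.000145 at the preset correlation. By fry they were 0.0875 and 0.00187, and by the exact sign-flip test on list means, lower in 7 and in 8 of 10 replicates, 0.132 and 0.0515.

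Genes that DRG neurons induce after nerve injury were mostly lower in DN. Of 44 tested, 26 fell and 5 rose (27 and 6 adjusted over the list alone), with a median log2 change of -0.29. Sox11, a transcription factor of axon regeneration, fell 2.03-fold (56.8 ± 12 against 115 ± 25.7 CPM), the adhesion gene Flrt3 1.86-fold and Sema6a 1.65-fold, and Atf3, Cckbr, Nts, Ecel1 and Sez6l are also members. The 5 that rose were Nptx1 (log2 fold change 0.74), Bdnf (0.55), Cacna2d1 (0.45), Stat3 (0.28) and Klf7 (0.28), chosen after their values were seen. The list's adjusted p was 5.29e-20 by camera at the preset correlation and 0.0102 with an estimated correlation, and its mean was lower in 10 of 10 replicates (mean log2 difference -0.64, exact sign-flip test, adjusted p = 0.00944).

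Nociceptor genes were mostly higher in DN. Of 38 tested, 27 rose and 3 fell (30 and 3 adjusted over the list alone), with a median log2 change of 0.72. Besides Mrgprd, Tac1 and Ptgir, Asic1 rose 2.61-fold, from 7.12 ± 3.23 to 17.8 ± 5.44 CPM. The 3 that fell were the acid-sensing channel Asic3, 2.48-fold lower at 10.8 ± 3.65 against 27.2 ± 10.3 CPM, and the glial-factor receptors Ret (log2 fold change -0.79) and Gfra3 (-0.76), of which the last 2 were chosen after their values were seen. The list's adjusted p was 1.00e-28 by camera at the preset correlation and 0.0392 with an estimated correlation, and its mean was higher in 10 of 10 replicates (mean log2 difference 0.74, exact sign-flip test, adjusted p = 0.00944).

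Genes shared by most sensory neurons moved both ways: of 32 pan-neuronal and sensory identity genes, 11 rose and 6 fell (15 and 7 adjusted over the list alone). Avil rose 1.67-fold and Nsg2 2.05-fold, while Tubb3, the neuronal tubulin gene, fell 1.65-fold from 985.5 ± 182.8 to 602 ± 130.7 CPM and Slc17a6, a vesicular glutamate transporter gene, fell 1.84-fold. Camera did not call this list (adjusted p = 0.0594, and 0.724 with an estimated correlation). Its mean was higher in 9 of 10 replicates (mean log2 difference 0.135, exact sign-flip test, adjusted p = 0.0566). Of 28 low-threshold mechanoreceptor and proprioceptor genes, 5 rose, among them Piezo2 (1.42-fold), Kcna2 (1.30-fold) and Asic2 (1.70-fold), and 3 fell, led by Fam19a4 (6 and 4 adjusted over the list alone). The others were Cntnap2 and Etv1 among the rises and Calb1 and Heg1 among the falls, chosen after their values were seen. The list's median was 0.01 and its mean over replicates -0.03, which differ in sign, and its adjusted p was 0.894 (0.956 with an estimated correlation).

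Of 27 voltage-gated potassium channel genes, 13 rose and 3 fell (14 and 5 adjusted over the list alone). Kcnd1 rose 1.93-fold, Kcnb2 1.86-fold, Kcns3 and Kcnab1 1.66-fold each, and the falls included Kcnv1 and Kcnc4, chosen after their values were seen. Of 34 synaptic vesicle and release genes, 13 rose and 2 fell (17 and 3 adjusted over the list alone), with Scg3 up 2.41-fold from 156.7 ± 32.2 to 376 ± 106 CPM, Sv2a 1.87-fold and Syt7 1.73-fold, and with Pcsk1, a prohormone convertase, down 2.19-fold. Of 39 axon growth and cytoskeleton genes, 3 rose and 9 fell (6 and 13 adjusted over the list alone), including Gap43, a growth cone gene, at 1.71-fold lower, Itga7 at 1.30-fold lower and Coro1a at 2.23-fold higher. Prph and Dpysl3, chosen after their values were seen, were the other rises. With an estimated correlation the adjusted p was 0.438 for potassium channels, 0.534 for synaptic genes and 0.541 for axon genes, against 0.000145, 8.31e-05 and 0.00258 at the preset correlation. By fry they were 0.00857, 0.0461 and 0.171, so the axon list did not pass there. By the exact sign-flip test on list means they were 0.0142, 0.0142 and 0.00944. In DN against untransduced cultures the same exact test gave 0.151, 0.085 and 0.704.

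Of 33 ATF4 and unfolded protein response genes, 15 rose and none fell (15 adjusted over the list alone). Slc7a5, an amino acid transporter gene, rose 1.85-fold from 109 ± 8.79 to 205 ± 42.3 CPM, Chac1 and Atf5 rose 1.65-fold each and Shmt2 1.33-fold, each in 10 of 10 replicates. The list's mean was higher in 10 of 10 replicates (exact sign-flip test, adjusted p = 0.00944), while camera gave 4.34e-07 at the preset correlation and 0.195 with an estimated correlation. Of 33 interferon response genes, 5 rose and none fell (5 adjusted over the list alone), among them Stat2 (1.44-fold), Oasl2 (1.33-fold), Ddx58 (1.25-fold) and Irf9, chosen after its value was seen. Camera did not call that list (adjusted p = 0.130, and 0.474 with an estimated correlation), and its mean was higher in 9 of 10 replicates (exact sign-flip test, adjusted p = 0.0340).

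Of 29 p53 target genes, 6 fell and 2 rose (7 and 2 adjusted over the list alone), the falls led by Perp (1.37-fold), Plk2 (1.13-fold), Btg2 (1.21-fold) and Cdkn1a (1.14-fold), and the rises being Rrm2b and Plk3, chosen after their values were seen. Of 23 NF-kB and cytokine genes, Tnfaip3 (1.14-fold) and Csf1 (1.16-fold) fell, and 0 passed when adjusted over the list alone. Lif and Nfkb2 had adjusted p of 0.0853 and 0.0867. Of 42 extracellular matrix remodelling genes, 4 fell (4 adjusted over the list alone), among them Adam8, a metalloprotease gene (2.66-fold), Plaur and Mmp19 (1.31-fold). Tgfbi was the 1 of 22 TGF-beta and YAP response genes that fell, with 1 adjusted over the list alone. The adjusted p of these 4 lists was 0.000921, 0.000852, 0.000210 and 0.00417 by camera at the preset correlation, and 0.263, 0.410, 0.541 and 0.541 with an estimated correlation. By fry it was 0.00309, 0.0160, 0.125 and 0.148. By the exact sign-flip test it was 0.00944 for p53 targets, with a mean lower in 10 of 10 replicates, 0.0252 for NF-kB genes, lower in 9 of 10, 0.132 for matrix genes and 0.0519 for TGF-beta and YAP genes.

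Markers of other cell types that passed the threshold are to be read beside 2054 of 18063 over all genes tested. The Schwann cell list was not below that share. Of 21 satellite glia markers, Glul fell 1.33-fold. Of 25 Schwann cell markers, Ngfr, which neurons also express, rose 1.80-fold and Cadm1 1.21-fold, while S100b fell 1.58-fold and Egr2 1.15-fold. Thy1, which is also a neuronal gene, fell 1.39-fold among 22 fibroblast markers, Csf1r 1.26-fold among 21 macrophage markers and Mcam 1.22-fold among 15 pericyte and smooth muscle markers. Among 18 endothelial markers, Flt1 fell 1.97-fold and Tek rose 1.55-fold. Of 34 proliferation genes, Ect2 fell 1.12-fold. Adjusted over the list alone, 1 satellite glia, 2 and 2 Schwann cell, 1 fibroblast, 1 pericyte, 1 and 1 endothelial, 0 macrophage and 0 proliferation genes passed. Camera at the preset correlation called the satellite glia (adjusted p = 0.0120), macrophage (0.0424) and proliferation (0.000706) lists as lower, with 0.541, 0.541 and 0.534 from an estimated correlation. It did not call the Schwann cell (0.248), fibroblast (0.142), endothelial (0.291) or pericyte (0.291) lists. The median log2 change of each of these cell type lists was below 0, from -0.036 for Schwann cell to -0.264 for macrophage markers. By the exact sign-flip test on list means none passed, with adjusted p from 0.138 to 0.385.

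Members of the metabolic lists that passed the threshold are to be read beside 2054 of 18063 over all genes tested. The cholesterol and glutathione lists were not below that share. Of 26 cholesterol synthesis genes, Fdft1 (1.22-fold), Fdps (1.19-fold) and Srebf2 (1.14-fold) rose and Lbr fell 1.14-fold. Of 24 glutathione and NRF2 target genes, Srxn1 fell 1.52-fold, and Trib3 (1.34-fold), Gsr (1.17-fold) and Gclc (1.14-fold) rose. Ndufv1 was the 1 of 39 oxidative phosphorylation genes that rose (1.18-fold), and Adar the 1 of 26 retrotransposon and LINE-1 restriction genes that rose (1.10-fold), a list whose median was -0.004 and mean 0.004, which differ in sign. No cytosolic ribosomal protein gene passed (0 of 40 by edgeR). Of 13 mitochondrially encoded genes, mt-Co1 fell 1.33-fold. Adjusted over the list alone, 3 and 1 cholesterol, 3 and 1 glutathione, 1 oxidative phosphorylation, 0 retrotransposon, 0 ribosomal and 3 mitochondrial genes passed. Camera called the mitochondrial list (adjusted p = 0.0126, and 0.551 with an estimated correlation) and did not call the cholesterol (0.323), glutathione (0.569), oxidative phosphorylation (0.421), retrotransposon (0.732) or ribosomal (0.920) lists.

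Of the 29 lists tested in DN against GFP, camera at the preset correlation called 17, of which 4 were higher and 13 lower. With an estimated correlation 2 were called, the nociceptor and the injury-induced lists. Fry, which asks whether the genes of a set move 1 way on balance without comparing them with other genes, called 10 lists, and the exact sign-flip test on list means also called 10.

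**Figure D3:**
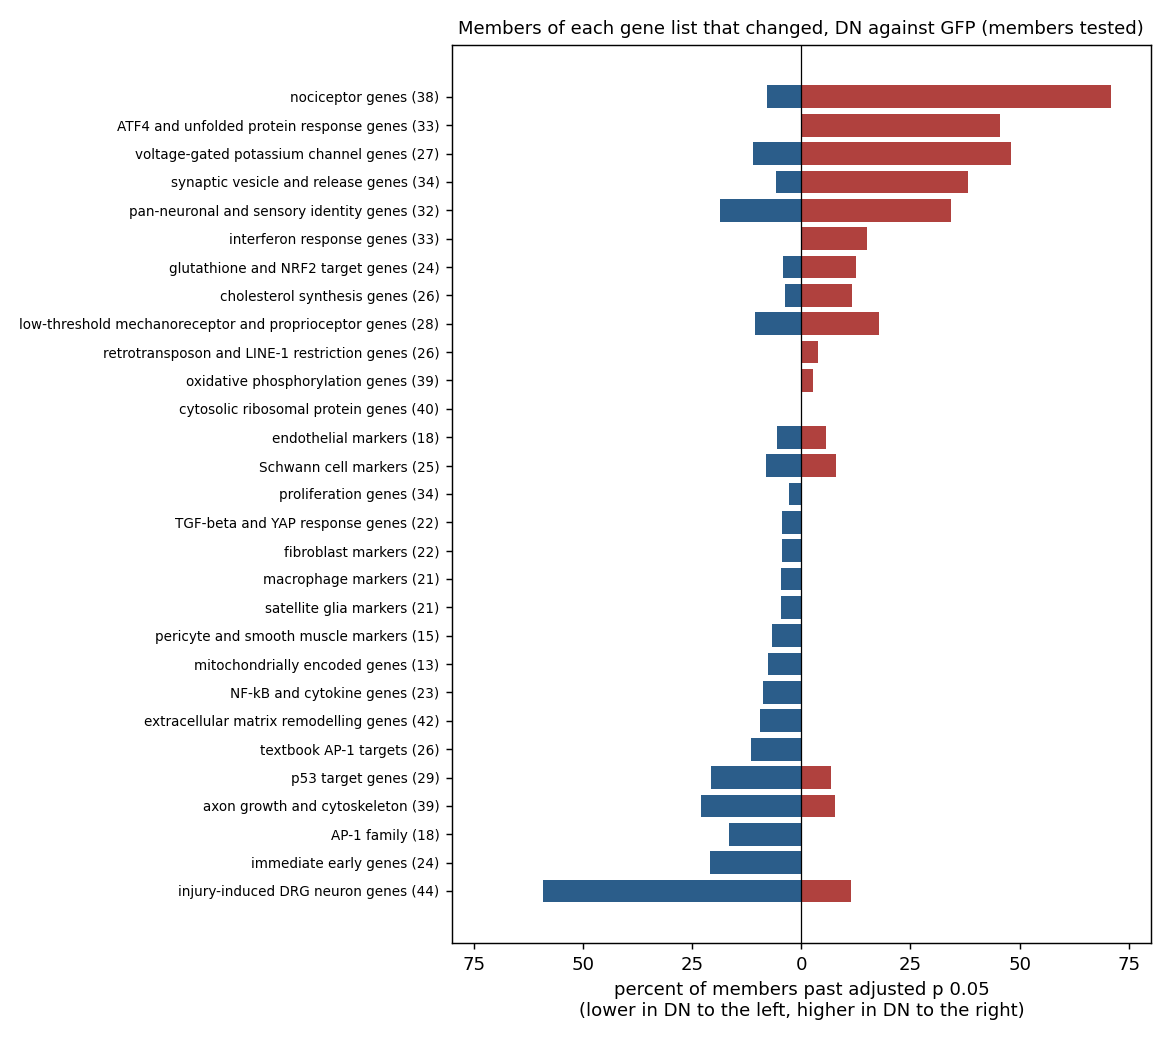
Bars give, for each of the 29 gene lists, the percent of tested members past the threshold in DN against GFP, higher to the right and lower to the left, with the number of members tested in parentheses. Nociceptor genes (27 higher and 3 lower of 38) and injury-induced genes (5 higher and 26 lower of 44) lie at the 2 ends.

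The comparison of DN with untransduced cultures measured the inhibitor and the vector together. Mrgprd was 11.9-fold higher in DN (log2 fold change 3.57, SE 0.32, adjusted p = 7.73e-08), Alkal2 5.93-fold, Tac1 5.02-fold, Ctxn3 4.73-fold, Hoxd1 4.59-fold and Chp2 4.30-fold. Cckbr was 6.77-fold lower (log2 fold change -2.76, SE 0.33, adjusted p = 4.40e-06), Serpinb1a 6.22-fold, Nts 4.91-fold, Trappc3l 4.79-fold, Sez6l 4.65-fold and Fam19a4 4.16-fold. These 12 genes moved in their direction in 10 of 10 replicates. Atf3 was at 111 ± 25.9 CPM in untransduced cultures against 56.4 ± 11.3 in DN, 1.96-fold lower.

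In this comparison 28 of 38 nociceptor genes rose and 3 fell (30 and 3 adjusted over the list alone), among them Ptgir, 4.20-fold higher, and Asic3, 2.27-fold lower. Of 44 injury-induced genes, 26 fell and 6 rose (28 and 8 adjusted over the list alone), with Sox11 2.00-fold and Flrt3 1.75-fold lower. Of 33 ATF4 and unfolded protein response genes, 13 rose and none fell (15 and 1 adjusted over the list alone), with Slc7a5 1.90-fold higher. Among 23 NF-kB and cytokine genes 5 fell and none rose (0 and 8 adjusted over the list alone): Tnfaip3 (1.24-fold), Lif (1.21-fold), Nfkb2 (1.19-fold), Nfkbia (1.16-fold) and Csf1. With an estimated correlation, the adjusted p of these lists was 0.0489, 0.0388, 0.132 and 0.185, against 1.01e-26, 5.04e-15, 3.82e-08 and 1.85e-05 at the preset correlation. Camera called 15 of 29 lists at the preset correlation and 2 with an estimated correlation, fry called 10, and the exact sign-flip test on list means called 3.

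By edgeR 2382 of 18063 genes were past the threshold in DN against untransduced, 1615 higher and 767 lower, with 173 rising and 134 falling by at least 2-fold. The share that was higher was 67.8% with TMM, 58.17% with median-ratio and 52.00% with upper-quartile factors, and 55.95% of 2917 genes by DESeq2. Without the block 2443 genes passed with culture set as a covariate, 1105 with no set term and 1333 when the fit held these 2 groups alone. The plain, dated and 7DIV sets alone gave 4335, 793 and 2 genes. The 7DIV fit held untransduced replicate 4, here within a compared group.

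Genes changed by DN against either control overlapped. Of the 2054 and 2382 genes, 1683 were called in both comparisons in the same direction, 1201 higher and 482 lower, and 0 in opposite directions. Mrgprd, Tac1, Ptgir, Alkal2, Cckbr, Serpinb1a, Nts and Atf3 were among them. Both comparisons share the 10 DN libraries, so overlap arises in part from that. Independent lists of these sizes would share 154.9 genes in the same direction. Log2 fold changes correlated at r = 0.864 across genes, against 0.472 to 0.514 in 20 simulations of unchanged groups. Their covariance was 0.109 against a simulated mean of 0.0186. In those simulations no gene was called in both. They held no condition effect, so hardly any call was possible. That 0 does not show how much of the overlap comes from the shared libraries. When odd replicates gave DN against GFP and even replicates DN against untransduced, no library was shared. Of 2782 and 170 genes, 168 were then called in both in the same direction, against 13.7 in the same direction for independent lists. With odd and even exchanged these values were 212 of 213 and 3071, against 19.5.

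The comparison of GFP with untransduced cultures measured transduction with the control vector. No single gene passed the threshold: edgeR, DESeq2 and limma each called 0 genes, with 373, 531 and 369 at an unadjusted p under 0.05, and the smallest adjusted edgeR p was 0.998. Mrgprd was at 3.59 ± 2.40 CPM in GFP and 3.95 ± 2.42 in untransduced cultures, Atf3 at 113.5 ± 33.1 and 111 ± 25.9, and Serpinb1a at 186 ± 41.3 and 178 ± 33.8. In the plain set alone 3 genes passed. Changes of 1.5-fold were recovered for 88% of simulated genes at this group size in the comparison of DN with untransduced. Those genes had an average above 0 log2 CPM and no simulated library stood apart, so this share need not hold for GFP against untransduced. The 373 of 18063 genes at an unadjusted p under 0.05 by edgeR are fewer than unchanged genes would give on average. The 0 calls therefore do not rule out changes of that size.

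Mitochondrially encoded genes were the list furthest from 0 in GFP against untransduced. Their median log2 change was 0.54, with mt-Co1 at 3127 ± 977 against 2244 CPM (1.38-fold), mt-Cytb 1.42-fold, mt-Nd5 1.52-fold and mt-Nd6 1.34-fold higher, each higher in at least 9 of 10 replicates. Of 13 members, 8 passed when adjusted over the list alone and 0 over all genes tested by edgeR. Camera gave an adjusted p of 8.42e-20 at the preset correlation and 0.0897 with an estimated correlation, and the list's mean was higher in 10 of 10 replicates (exact sign-flip test, adjusted p = 0.0566). The share of all counts in mitochondrially encoded genes was 0.911% ± 0.436 (SD, n = 10) in GFP, 0.621% ± 0.355 in untransduced and 0.756% ± 0.392 in DN cultures. It was higher in GFP than in untransduced in 9 of 10 replicates (mean log2 difference 0.57, exact two-sided sign-flip test, p = 0.00391), by 0.21 in the plain, 1.24 in the 7DIV and 0.34 in the dated set. Without replicate 4 that difference was 0.52 (p = 0.00781 by the same exact test). DN against GFP gave -0.31 (p = 0.0527), and -0.41 (p = 0.00781) without replicate 4, by the same exact test. The last value leaves out DN and GFP replicate 4, since untransduced replicate 4 is in neither group. DN against untransduced gave 0.26 (higher in 6 of 10 replicates, exact p = 0.236), and 0.10 (exact p = 0.473) without replicate 4. By set it gave -0.12 in the plain, 1.09 in the 7DIV and -0.07 in the dated set.

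**Figure D4:**
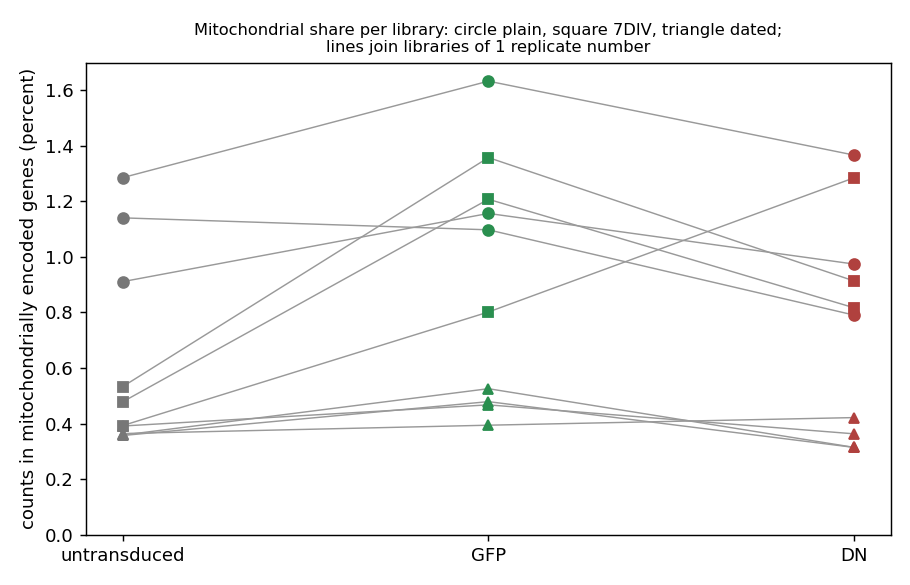
Each point is 1 library, with the percent of gene counts in mitochondrially encoded genes on the vertical axis and condition on the horizontal axis, and lines join the libraries of 1 replicate number. The share was higher in GFP than in untransduced in 9 of 10 replicates, and within each condition the libraries of the dated set lie lowest.

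Among the other lists in GFP against untransduced, camera at the preset correlation called satellite glia markers (adjusted p = 0.000204, median log2 change 0.07), cholesterol synthesis genes (0.00473), Schwann cell markers (0.0118), oxidative phosphorylation genes (0.0155), proliferation genes (0.0250) and axon genes (0.0409) as higher and NF-kB genes (0.0321) as lower. Cdh19, a glial cadherin gene, was 1.11-fold higher in 10 of 10 replicates and did not pass the threshold. With an estimated correlation the adjusted p of each of these 7 lists was 0.998. With all libraries 8 of 29 lists were called, 7 higher and 1 lower. Without untransduced replicate 4 the count was 4, 1 higher and 3 lower, of which 2 were among the 8, the mitochondrial list as higher and the NF-kB list as lower. The count was 0 with an estimated correlation, by fry or by the exact sign-flip test. The nociceptor, potassium channel, extracellular matrix, endothelial, pericyte, fibroblast and interferon lists had medians and means that differ in sign from each other or from the test, all with magnitudes under 0.11 on the log2 scale.

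The DN effect was compared between culture sets. It differed for 66 of 18063 genes by the edgeR interaction test, of which 39 were also past the threshold in DN against GFP and 37 had 1 direction in all 3 sets. The 6 smallest p belonged to Coro1a, Dgkg, Cckbr, Sertad4, Gm14539 and Nts. The fall of Cckbr was -5.06 on the log2 scale in the plain set, -1.65 in the 7DIV set and -2.73 in the dated set (adjusted p = 0.00641), and that of Nts was -4.11, -1.68 and -2.50 (adjusted p = 0.0122). Coro1a rose by 2.07, 0.54 and 0.90, Dgkg by 2.60, 1.31 and 1.16, and Sertad4 by 1.5, 0.53 and 0.56. Gm14539, a gene not past the threshold in DN against GFP, had -0.17, 0.59 and -0.80. The count was 0 without replicate 1 or without replicate 3, both of the plain set, and 544 without untransduced replicate 4.

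Reads in long interspersed elements (LINEs), a class of retrotransposons, came from a separate table of 205758 intervals with a median length of 24 bp. LINE intervals were 8.329% of these and held 201820 reads, while SINE intervals were 54.24% of the intervals and rRNA intervals held 55.16% of the reads. Exons held 38.41% of LINE reads, genes outside exons 42.98% and the rest of the genome 18.61%. LINE reads per 1e+06 gene reads were 213 ± 50.1 (SD, n = 10) in DN, 224 ± 54.7 in GFP and 322 ± 382 in untransduced cultures, where 1 library, untransduced replicate 4, had 1400. The mean log2 difference was -0.07 for DN against GFP (higher in 4 of 10 replicates, exact two-sided sign-flip test, p = 0.471), -0.22 for DN against untransduced (p = 0.615, and 0.03 with p = 0.773 without replicate 4) and -0.15 for GFP against untransduced (p = 0.982, and 0.09 with p = 0.0391 without replicate 4). Adjusted over the 3 comparisons these were 0.922, 0.922 and 0.982.

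Of 80 LINE subfamilies tested by edgeR, L1MB2 was lower in DN than in GFP (log2 fold change -2.39, SE 0.28, adjusted p = 6.38e-08) and than in untransduced cultures (-2.61, SE 0.28, adjusted p = 9.68e-09). Of its 2199 reads, 85.99% lay in 1 interval, on chromosome 10 from 34109352 to 34109375, inside Trappc3l and outside its exons. Trappc3l itself fell by 2.28 on the log2 scale. L1ME3D was higher in DN than in untransduced cultures (0.75, SE 0.19, adjusted p = 0.0177), with 98.26% of its 3959 reads in 1 interval of an exon of Sh3bgrl2, and did not pass against GFP (0.56, adjusted p = 0.212). L1MB4 (0.84), L1MA4A (-0.69), Lx2B (0.69) and L1MEg (-0.58) had the next smallest p in DN against GFP and did not pass, and neither did L2b (-0.96) in DN against untransduced. In GFP against untransduced 0 subfamilies passed by edgeR and by DESeq2, with 0 at an unadjusted p under 0.05 by either, and the 6 smallest p belonged to L1MD1, L1MDa, L2b, L1ME3E, L1MA9 and L1MD2. SINE reads per gene read were lower in DN than in GFP in 9 of 10 replicates (mean log2 difference -0.31, exact sign-flip test, p = 0.00586, adjusted over 12 comparisons 0.0703). That comparison was added after the data were seen.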

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

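The tests of neuron share, of the single L1MB2 interval and of read number in untransduced replicate 4 were chosen after the results were seen, as were the 6 nuclear RNAs, the list-mean test and the fits without that library. The other tests had been chosen before.

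Nociceptor genes were higher and injury-induced genes lower in DN than in GFP. A larger share of neurons in DN cultures would raise all neuronal genes by about the same amount, but the pan-neuronal list had a median log2 change of 0.157 (95% interval over members -0.024 to 0.343) against 0.721 (0.474 to 0.991) for nociceptor genes and -0.289 (-0.620 to -0.188) for injury-induced genes, which neurons also express. A trend with gene length left at least 98.4% of either median when it was taken off. The intervals over members describe the spread between genes, not between cultures. Over replicates, the mean log2 difference of the pan-neuronal list was 0.135, higher in 9 of 10 (exact sign-flip test, adjusted p = 0.0566). The median of each glial, fibroblast, macrophage, endothelial and pericyte list was below 0, from -0.036 to -0.264. A smaller rise in the share of neurons beside other changes was therefore not excluded, and the pan-neuronal interval reaches 0.343. Also open are a direct or indirect effect of AP-1 inhibition on these genes and a shift between kinds of neurons, for example better survival of some. Neither that effect nor that shift was tested, so a change of expression within the neurons remains a hypothesis.

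The reads of L1MB2 were lower in DN than in GFP. Without the 1 interval inside Trappc3l the log2 fold change of L1MB2 went from -2.386 (95% interval -2.948 to -1.824) to -0.420 (-1.696 to 0.856, p = 0.507 by edgeR), on 308 reads, so the call ended both because the fold was smaller and because the interval was wider. Trappc3l fell by 2.282, close to the fold of L1MB2 with the interval, and a candidate explanation is that these reads came from Trappc3l transcripts. A change of the element elsewhere of up to the bounds of that interval was not excluded. For L1ME3D against untransduced cultures, leaving out the interval in Sh3bgrl2 moved the fold from 0.754 to -0.491 on 69 reads, beside 0.657 for Sh3bgrl2.

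Untransduced replicate 4 stood apart from the other libraries. Thinned to its total, untransduced replicates 5 and 6 stayed lower in the median of Malat1, Neat1, Meg3, Kcnq1ot1, Miat and Snhg11 by 3.432 on the log2 scale. For Malat1 the difference was 2.969 before thinning and 2.972 after it. Thinning leaves the expected share of each RNA unchanged, so this result was set beforehand. It cannot decide on other causes that go with a low total. A larger share of unspliced nuclear RNA is a candidate explanation. LINE reads per gene read were 3.804 higher on the log2 scale in genes outside exons and 0.914 higher in exons than in the other untransduced libraries. The difference was 2.89, with SDs of 0.600 and 0.168 among those 9 libraries. Outside genes LINE reads were 1.801 higher (SD 0.285), a rise that unspliced RNA of annotated genes would not by itself give. Whether this arose in the culture or at extraction was not tested, and no biological explanation was tested, since no group of the design sets this library apart.

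In 52 measures over 3 groups, 156 tests of the highest or lowest library found 15 that lay far from the rest, where chance gives about 1 in 20, or 7.8, and 9 of the 15 were of untransduced replicate 4. That library had 10.7 M counts where the next lowest had 24.1 M. Per 1e+06 gene reads it had 1400 LINE reads against 156 to 274 in the other untransduced libraries, 16300 SINE reads against 1440 to 2810, and 1440 LTR reads against 189 to 356. It was at 2.43 CPM of Fosb (others 7.23 to 10.7), 96.0 of Ecel1 (51.4 to 68.0), 218 of Mafg (122 to 166), 22.2 of Alkal2 (1.74 to 10.6) and 23.4 of Pde11a (5.38 to 14.2).

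The other 6 libraries that lay far from their group were these. DN replicate 3 had 2860 SINE reads per 1e+06 gene reads against 1400 to 2080. DN replicate 6 had 14.8 CPM of Nts against 0.943 to 7.83, and DN replicate 7 had 13.4 of Tgfbi against 1.09 to 7.40. GFP replicate 6 had 3.60 CPM of Sprr1a against 0.276 to 1.99, GFP replicate 4 had 9.36 of Mrgprd against 0.852 to 4.81, and GFP replicate 10 had 51.0 of Sez6l against 115 to 157.

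The DN effect against GFP differed between the 3 culture sets for 66 genes by an interaction test. The adjusted p was 0.00483 for Coro1a, 0.00496 for Dgkg, 0.00641 for Cckbr, 0.00724 for Sertad4, 0.00961 for Gm14539 and 0.0122 for Nts. Regrouping the 10 replicates into 3 sets of the same sizes gave as many genes in 1 of 50 arrangements, the real one, and the highest other gave 0. That share is under 0.05, and 50 arrangements can give none smaller. The number was nevertheless 0 without replicate 1 or 3 and 7 without replicate 2 or 9, against 196 without replicate 4, so it rests on single replicates.

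Swapping labels within replicates tested whether the counts arise by chance. For DN against GFP, 1 of 50 arrangements, the real one with 2054 genes, gave as many, and the highest other gave 1549 with 1 replicate swapped. That share is under 0.05, and 50 arrangements can give none smaller. The same held for DN against untransduced (1 of 50, 2382 against 1127 with 2 replicates swapped) and for the genes called in both (1 of 50, 1683 against 0). For GFP against untransduced all 50 arrangements gave 0 genes. Counts of lists called by camera at the preset correlation did not exclude chance: 9 of 50 arrangements gave at least the 17 of DN against GFP (highest other 20), 18 of 50 the 15 of DN against untransduced (highest other 20) and 43 of 50 the 8 of GFP against untransduced (highest other 18). For LINE subfamilies, 2 of 50 arrangements gave at least 1 in DN against GFP (the real value and the highest other were both 1), a share just under 0.05. In DN against untransduced 3 of 50 gave at least 2, a share not under 0.05. The highest other gave 19 with 4 replicates swapped, and what produced that count was not tested. In GFP against untransduced all 50 gave 0.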

How the results depend on the processing

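Fits without untransduced replicate 4 alone, LINE intervals outside genes and the list-mean test were added after the data were seen. The cause of a change was not tested except where fewer samples or a stricter test give it. Of the values of single genes and lists under alternatives, 8075 kept their direction and side of the threshold, 242 newly passed, 881 no longer passed and 13 reversed. Of the counts and other main values, 209 stayed within 1.5 times or kept their direction within their spread, 56 moved and 1 reversed. The LINE results rest on 201820 reads in 142 subfamilies, of which 80 had enough reads to be tested. All alternatives chosen in advance were run.

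The genes past the threshold in DN against GFP numbered 973 with no block and no set term, 603 against a fold of 1.2, 587 without the plain set, 4004 in it alone, 3186 without the 7DIV set, 10 in it alone, 1217 without the dated set and 751 in it alone. Leaving out 1 replicate number, or untransduced replicate 4 alone (3239), gave 1441 to 3239. For DN against untransduced they were 1105 with no block and no set term, 1333 with these 2 groups alone, 601 against a fold of 1.2, 610 without the plain set, 4335 in it alone, 2 in the 7DIV set alone and 793 in the dated set alone, and 1644 to 2979 with 1 replicate left out. For GFP against untransduced 3 passed in the plain set alone and 0 under every other alternative run. Genes whose DN effect differed between sets numbered 27 by limma, 506 with no filter, 8 with no block and 0 to 544 with 1 replicate left out, the 544 without untransduced replicate 4. Genes called in both comparisons numbered 986 at an adjusted p under 0.01, and 168 and 212 between odd and even replicates, which share no library and hold fewer samples. Odd replicates alone called 2782 genes in DN against GFP and 3071 in DN against untransduced, more than all replicates together. Even replicates, which include untransduced replicate 4, called 213 and 170. Fewer samples alone therefore do not account for the lower overlap, and its cause was not tested.

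Lists called in DN against GFP were 2 with an estimated correlation, 10 by fry and 10 by list means, and in DN against untransduced 2 with an estimated correlation and 3 by list means. In GFP against untransduced they were 4 without the 7DIV set, 0 with an estimated correlation, 0 by fry, 0 by list means and 4 to 12 with 1 replicate left out, the 4 without replicate 4 or without untransduced replicate 4 alone. LINE subfamilies called were 2 in DN against GFP without the 7DIV set and 1 to 2 with 1 replicate left out. In DN against untransduced they were 1 with LINE totals as library sizes, 1 outside genes, 1 without the plain set, 1 without the dated set and 1 to 3 with 1 replicate left out.

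LINE reads per gene read in GFP against untransduced reversed to 0.086 without replicate 4 (range -0.189 to 0.086). Thy1 in DN against untransduced was 0.036 in the 7DIV set alone. Lists whose camera direction reversed had these adjusted p. Without the 7DIV set the oxidative phosphorylation list had 0.0298 in DN against GFP, and in DN against untransduced it had 0.00359, the ribosomal list 0.0253 and the mitochondrial list 0.0368. The next have the range over replicates left out in parentheses. The list axon growth and cytoskeleton, GFP vs untransduced (0.000265 to 0.234), had 0.234 without replicate 4, 0.201 without the 7DIV set and 0.198 without untransduced replicate 4. The list voltage-gated potassium channel genes, GFP vs untransduced (0.0360 to 0.976), had 0.0360 without replicate 10. The list oxidative phosphorylation genes, GFP vs untransduced (0.00238 to 0.649), had 0.185 without the 7DIV set and 0.505 without untransduced replicate 4. The list glutathione and NRF2 target genes, GFP vs untransduced (0.00405 to 0.997), had 0.0274 without replicate 4 and 0.00405 without untransduced replicate 4.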

Other observations

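The comparison of LINE intervals outside annotated genes was chosen after the data were seen. So were the comparisons of LTR and rRNA reads and of the mitochondrial share between culture sets.

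Cultures of the 3 sets differed in the share of mitochondrially encoded genes, which in the dated set lay below the other sets within each of the 3 conditions. It was 0.357% to 0.391% in untransduced, 0.394% to 0.525% in GFP and 0.314% to 0.421% in DN cultures of the dated set. This difference was not tested. Reads of LTR intervals per gene read did not differ past the threshold between conditions: the mean log2 difference was -0.10 for DN against GFP (exact sign-flip test, p = 0.303), -0.22 for DN against untransduced (p = 0.547) and -0.13 for GFP against untransduced (p = 0.996). For rRNA intervals the values were -0.03 (p = 0.709), 0.19 (p = 0.279) and 0.22 (p = 0.107). Untransduced replicate 4 stood at -9.44 in log2 LTR reads per gene read, against -12.37 to -11.46 in the other untransduced libraries. The negative sign of the LTR means against untransduced rested on this library. LTR reads were higher in GFP than in untransduced in 8 of 10 replicates, and higher in DN than in untransduced in 4 of 10. LINE intervals outside annotated genes gave 1 of 30 subfamilies past the threshold by edgeR in either comparison with DN. The log2 fold change of LINE L1MB4, DN vs GFP, was 1.52 (adjusted p = 0.00776, range over its alternatives 0.00776 to 0.986) and that of LINE L1MB4, DN vs untransduced, was 1.55 (adjusted p = 0.00751, range 0.00751 to 0.557). With all its intervals, which held 699 reads over all libraries, L1MB4 did not pass in either comparison. Whether its reads lay mostly in 1 interval, as those of L1MB2 and L1ME3D did, was not tested.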
